A study of Danio rerio with 6 samples.

How the data were processed

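RNA from whole tailbud-stage zebrafish embryos was measured in 6 samples, 3 of etsrp-injected embryos and 3 of uninjected controls. Per the labels, the samples of about 150 embryos came from 3 separate batches, the labels' protocols describe random-primed Cy3 labelling of double-stranded cDNA, and the arrays carry 60-base probes designed on the Zv6 genome assembly. The array held 387477 probes for 32291 sequences, with a median of 12 probes per sequence, and 1830 random-sequence control probes.

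The deposited files held probe and gene values on a linear intensity scale. Per the file headers, the scanner intensity of each probe was extracted with NimbleScan 2.4.27, with no normalization, and these values were used here. Per the series design text, the authors' own intensity values were made by quantile normalization across arrays followed by RMA, and RMA also stands in the submitters' processing notes. The authors' deposited gene table held 19981 of the sequences. It differed from a median polish of the authors' deposited normalized probe values by a median of 0.003979 on the log2 scale. The rule by which its sequences were chosen is not given in the sources used here. It served only as an alternative, and 1588 sequences tested here were outside it. Across genes, its fold changes correlated with those computed here at 0.9867.

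From the scanner intensities, background was corrected with normexp (saddle-point fit, offset 50). Arrays were quantile-normalised and log2-transformed, and probes of a sequence were summarised by median polish, in limma 3.58.1 and R 4.3.3. An array's background was the median of its random-sequence control probes. A sequence was tested where at least 1 group mean lay 2-fold or more above background, after the criterion in the series design text, which left 21564 sequences. The test was limma (lmFit and eBayes) of the 3 injected against the 3 control arrays with Benjamini-Hochberg adjustment at 0.05. The design text also names a p limit but no test, so limits on unadjusted p were run as alternatives. Different normalizations moved the median difference of all genes by at most 0.03 on the log2 scale.

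A sequence less than 2-fold above background on all 3 arrays of a group had only a bound there. Its change is given as at least N-fold: the bright group's mean against the mean of, per array, the higher of that limit and the measured value. All folds are on the scale of normalised intensities after the offset of 50, which understates changes of dim transcripts. Strong signals are compressed on arrays, so that large folds are likewise no measure of RNA amount.

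Array sequences were named through an NCBI RefSeq gene table of the assembly GRCz12tu. It was used for names only, since the builds differ, and no coordinates are given. A single symbol was found for 12587 sequences (10828 by accession, 635 by gene identifier and 1124 by synonym). Several symbols matched 42 sequences and none matched 19662, mostly predicted transcripts of the older assembly, which stayed in the tests without a name. Where several sequences carried 1 symbol, the one with the highest mean over all arrays stood for the gene, and differing sequences are described.

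The genes described were chosen by a rule fixed before the data were examined. It takes the injected gene, then the 10 largest rises and the 10 largest falls. These come from sequences past the threshold with non-overlapping groups, signal above background in at least 1 group and a single gene symbol that is no clone name. It then takes up to 4 members of each gene list with the smallest p. No fall passed. Members of lists without a call, and some members of the others, are covered by their list's summary.

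The 18 gene lists were fixed at the same time. They cover angioblast and endothelial transcription factors, endothelial surface, junction and signalling genes, VEGF and Notch pathway genes, primitive erythroid genes, myeloid and leukocyte genes, presomitic and paraxial mesoderm, axial mesoderm, neural plate and brain, and endoderm. They also cover heart, lateral plate and pronephros, epidermis and enveloping layer, neural crest and placode, primordial germ cells, blastula and early gastrula, p53 response, interferon response, cell cycle and housekeeping genes. Some vascular markers are known from earlier work on etsrp, so the vascular lists are not independent of the gene studied. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 18 lists. Of the 9 lists called, 3 were also called with an estimated correlation, and 3 by fry, which tests whether a list's genes move, on balance, one way. These were the 3 vascular lists. With the batch block none of the 3 was called by fry (adjusted p = 0.05894, 0.05894 and 0.05904). In the blocked fit with an estimated correlation, camera gave an adjusted p of 0.2407 for each of the 3. The presomitic, axial and epidermis lists had the same value, so it does not tell these lists apart.

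Labels give both groups the replicate numbers 1 to 3. Deviations from group means correlated at 0.355, 0.634 and 0.463 between same-numbered samples, each above the limit of 0.1 set for pairing. Between different numbers, control replicate 1 and injected replicate 3 also correlated, at 0.469, as did control replicate 3 and injected replicate 1, at 0.118. The labels do not say which samples shared a batch. By the limit set beforehand the numbers were read as shared batches, a reading that the correlations between different numbers leave uncertain. The fit with the number as a block is given where it changed a call.

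The test was tried on simulated data: 10 simulations of 21564 sequences on the scale of these arrays, with 200 changed. Changes of 1, 2 and 3 on the log2 scale were recovered in 17.4%, 71.8% and 90.0% of cases, and 3.65% of calls were false. The simulated noise was independent between sequences and alike in both groups, without batches, a background floor or a noisier array. These shares therefore need not hold for the real arrays. Alternatives covered background correction, normalization, probe summary, filter, the authors' tables, the block, a variance trend, each array left out, array weights and other set tests.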

Results

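Gene expression was measured in whole zebrafish embryos at the tailbud stage, the end of gastrulation. Embryos in 1 group had received about 50 pg of etsrp RNA by microinjection during the earliest cleavages, and the controls were uninjected. The gene etsrp (also called etv2) encodes an ETS-domain transcription factor required for the formation of blood vessel precursors. Each group held 3 samples, each of about 150 embryos, from 3 separate batches. Each sample was hybridised to its own one-colour oligonucleotide array with 387477 probes for 32291 transcript sequences. The median scanner intensity was between 578.78 and 764.11 on 5 of the arrays and 1095.1 on the array of injected replicate 2. The median of the random-sequence control probes, which match no zebrafish transcript by design, was 865 on that array and between 241.11 and 370.89 on the others. With 3 arrays per group, the number of arrays limits the precision of every value given here. The comparison of injected with control embryos asks which genes were higher or lower after the injection. With uninjected controls it cannot tell effects of etsrp apart from those of the injection itself.

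The injected gene itself was measured first. The normalised etsrp level was 8.58 ± 0.33 in controls and 15.31 ± 0.22 in injected embryos (log2, mean ± SD, n = 3 each). This was a rise of 6.73 ± 0.23 on the log2 scale (± SE), or 106-fold, with a limma adjusted p of 1.412e-05. An array-level exact permutation test of the same difference gave p = 0.1 (two-sided), which is the smallest p that 3 against 3 arrays can give. A second etsrp sequence on the array rose by 6.65 ± 0.23. All 24 probes of both sequences were higher on every injected array than on every control array, and none reached the scanner ceiling of 65535. The probes read injected and endogenous etsrp RNA together. In injected embryos single probes read from 8.22 (log2), for the probe that starts at base 13, to 15.93, for a probe that starts at base 481.

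**Figure D1:**
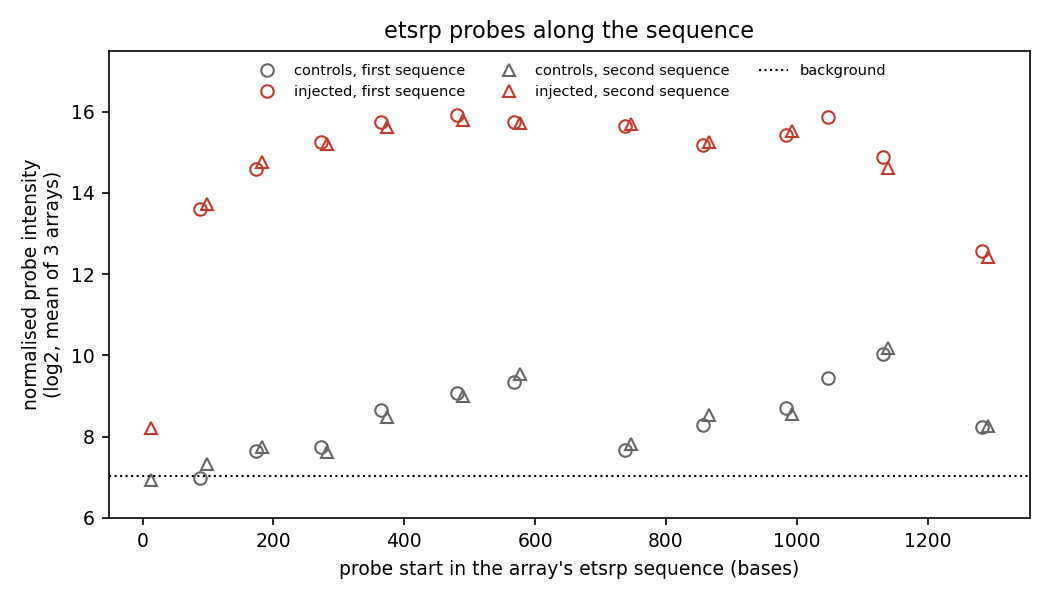
Normalised intensity (log2, mean of 3 arrays) of each etsrp probe against its start in the array sequence (bases), for controls in grey and injected embryos in red, with circles and triangles for the 2 array sequences and a dotted line at the mean background of the 6 arrays. The probe at base 13 reads 8.22 in injected embryos, and the next probes, at bases 88 and 98, read 13.60 and 13.72.

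The named transcripts with the largest rises after etsrp injection include genes of blood vessel and blood precursors. Expression of tal1, a basic helix-loop-helix factor of blood and endothelial precursors, rose at least 17.1-fold, from less than 2-fold above background in all controls to 12.05 ± 0.30 (log2, mean ± SD, n = 3). Expression of clec14a, an endothelial lectin, rose at least 9.91-fold, to 11.26 ± 0.83. The SH2-domain adaptor gene she rose 9.20-fold (log2 3.20 ± 0.23 SE), and fli1, an ETS factor of endothelial and blood cells, rose 7.89-fold (2.98 ± 0.26). The rise was at least 5.51-fold for egfl7, which encodes a secreted endothelial protein (to 10.42 ± 0.41), at least 5.46-fold for the aquaporin gene aqp8a.1 (to 10.40 ± 0.55) and at least 5.40-fold for the angiotensin receptor gene agtr2 (to 10.39 ± 0.45). The SoxF factor gene sox7 rose 5.08-fold (2.35 ± 0.28), the fli1-related gene fli1rs 4.71-fold (2.24 ± 0.25), and lmo2, which encodes a LIM-domain partner of tal1, 4.67-fold (2.22 ± 0.24). These 10 genes were the largest named rises besides etsrp by fitted value, an order that is uncertain where only a lower bound was measured. Their limma adjusted p ranged from 0.0001526 for tal1 to 0.02254 for sox7. A second lmo2 sequence, higher at least 1.52-fold, did not pass (adjusted p = 0.0814), but passed with the batch block (adjusted p = 0.01388).

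In all, 36 of 21564 tested sequences changed (limma, adjusted p below the threshold of 0.05), and each of them rose, with a fitted change above 2-fold. They carried 20 distinct gene symbols, with 14 sequences left unnamed. Unnamed sequences were among the largest rises, the largest of them at least 9.52-fold. Over all 36, the fitted log2 rises ranged from 1.41 to 6.73, with a median of 2.30. In 22 of the 36, all 3 controls were less than 2-fold above background, so that only a lower bound of the rise was measured, which in 1 unnamed sequence was below 2-fold (at least 1.59-fold). The 3 injected arrays lay above the 3 control arrays in all 36. Over all tested sequences the groups did not overlap in 6.94%, where chance gives 10%. Of the 432 probes of these 36 sequences, 393 were higher on every injected array than on every control array. The sequences were called from these same probes, so this share is no separate support for the calls.

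No sequence fell in the limma test, and the smallest adjusted p among lower values was 0.472. At an unadjusted p below 0.05, limma gave 495 higher and 98 lower sequences, and a two-sample test without pooled variance gave 531 higher and 174 lower ones. The totals, 593 and 705, are each a smaller share of the 21564 tested sequences than the 0.05 expected with no change. Single sequences among them are therefore not read as changed. At the same unadjusted threshold the balance was more even with the batch number as a block, at 761 higher and 511 lower. It was also more even with array quality weights, chosen after the data were seen, at 1604 and 1515. The weighted fit rested mostly on injected replicate 1. After adjustment, 126 sequences rose and 0 fell with the block, and these included all 36. Leaving out control replicates 1, 2 and 3 in turn left 5, 11 and 8 changed sequences. Leaving out injected replicates 1, 2 and 3 left 15, 59 and 12. The count was 8 with median scaling of the arrays and 9 without background correction.

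**Figure D2:**
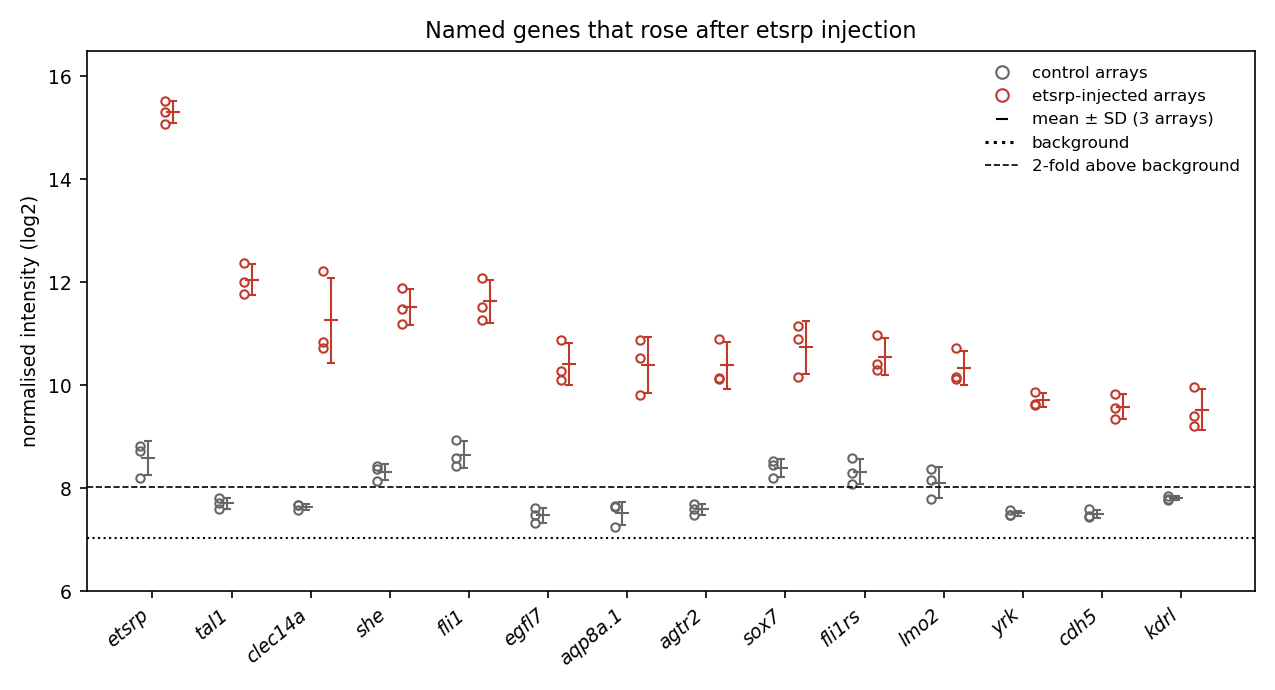
Normalised intensity (log2) on each array for the 14 named genes that rose, with controls in grey and injected embryos in red, bars for mean ± SD of 3 arrays, a dotted line at the mean background of the 6 arrays and a dashed line 2-fold above it. Injected tal1 arrays lie between 11.78 and 12.37 and control arrays between 7.59 and 7.80, which is below the dashed line.

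Transcription factors of angioblasts and endothelium, a list fixed before the data were examined, had 18 measured members. Of these, 5 rose (etsrp, tal1, fli1, sox7 and lmo2), 0 fell and 13 did not pass. With p adjusted over the list alone, 9 rose, adding hey2, and klf2a, erg and hhex, these last singled out after their values were seen. The level of hey2, a Notch-responsive gene of arteries, was higher at least 1.75-fold, at 8.76 ± 0.21 in injected embryos (adjusted p = 0.06861), and passed with the batch block (adjusted p = 0.01342). The median member difference was 0.61. The list was higher as a set (camera adjusted p = 1.633e-25), and without the injected gene itself, a setting chosen after the data were seen, it was too (5.374e-20, or 0.03805 with an estimated correlation). The adjusted p with an estimated correlation was 0.02643, and in the blocked fit with an estimated correlation it was 0.2407.

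Endothelial surface, junction and signalling genes had 39 measured members, of which 9 rose, 0 fell and 30 did not pass. Adjusted over the list alone, 22 rose and 0 fell. Besides clec14a, she, egfl7, aqp8a.1 and sox7, the 9 included yrk, a Src-family kinase gene, at least 3.37-fold, and cdh5, which encodes VE-cadherin, at least 3.10-fold. They also included kdrl, which encodes a VEGF receptor, at least 2.97-fold (adjusted p = 0.03986), and tpm4a, a tropomyosin gene named after its value was seen. A second yrk sequence, dim in all controls, did not pass (adjusted p = 0.3558), but passed with the batch block (adjusted p = 0.02603). Both kdrl sequences passed. The median member difference was 0.91, or 0.84 with dim members at their bound. The list was higher as a set (camera adjusted p = 2.413e-45). With an estimated correlation the adjusted p was 0.02643, and in the blocked fit with an estimated correlation it was 0.2407.

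Genes of the VEGF and Notch pathways had 27 measured members, of which kdrl alone rose. Adjusted over the list alone, 5 rose (kdrl, hey2, nrp1b, dll4 and flt4, the last singled out after its value was seen). The level of nrp1b, a VEGF co-receptor gene, was higher by 1.74 ± 0.33 on the log2 scale (adjusted p = 0.162), and passed with the batch block (adjusted p = 0.001729). The Notch ligand gene dll4 was higher by 0.68 ± 0.17 (adjusted p = 0.5494). The list was higher as a set (camera adjusted p = 1.831e-05). The adjusted p with an estimated correlation was 0.03805, and in the blocked fit with an estimated correlation it was 0.2407. The vascular lists overlap: kdrl, nrp1b, dll4, flt4, nrp1a, kdr, plcg1, notch1b and efnb2a are in the endothelial list too, and hey2 is in the angioblast list too. All 5 members that rose over the list alone are shared, and the VEGF and Notch list was not tested without its shared members. Its call is therefore not independent of those of the other vascular lists. The gene sox7 is in the angioblast and endothelial lists.

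Calls of single genes depended on the arrays kept. Of the 14 named genes that rose, etsrp, tal1 and she passed in all 6 fits that left out 1 array, and 11 did not pass in at least 1. Of the 14, 11 failed without control replicate 1, 6 without control replicate 2 and 9 without control replicate 3. Of the 14, 5 failed without injected replicate 1, 0 without injected replicate 2 and 5 without injected replicate 3. Among these 11, the highest adjusted p of a gene over the 6 fits ranged from 0.0529 for egfl7 to 0.298 for kdrl. All 14 kept their direction. With median scaling 10 of the 14 did not pass, and without background correction 7.

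**Figure D3:**
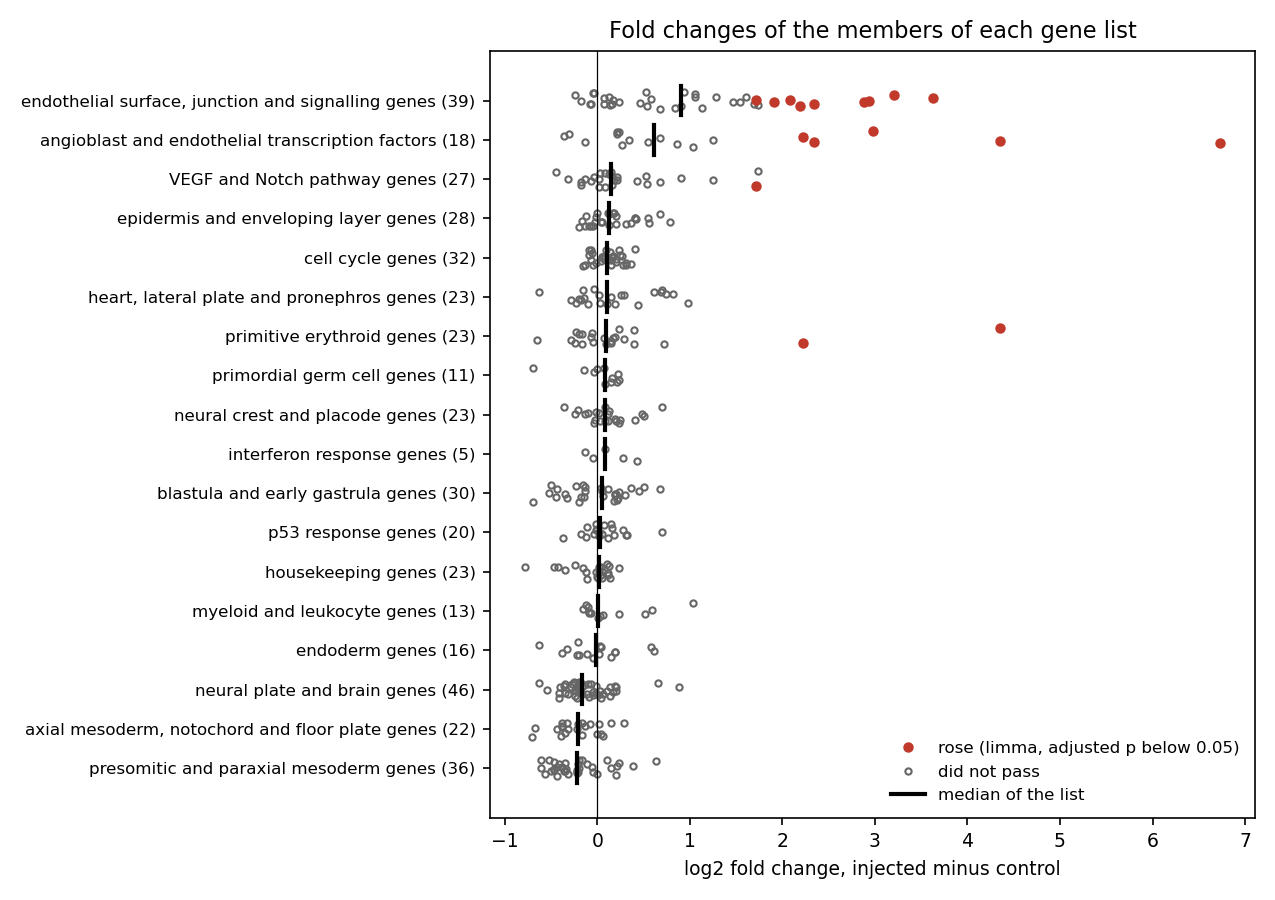
Log2 fold change (injected minus control) of each measured member of the 18 gene lists, with the number of measured members in brackets. Red points are members that rose in limma, open grey points did not pass, and black bars mark list medians, which range from -0.22 in presomitic and paraxial mesoderm genes to 0.91 in endothelial surface, junction and signalling genes.

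Blood lists gave few calls. Of 23 measured primitive erythroid genes, 2 rose, tal1 and lmo2, which are also in the angioblast list. The transporter gene rhag was higher by 0.72 ± 0.20 on the log2 scale (adjusted p = 0.7631) and the membrane skeleton gene epb41b at least 1.22-fold (adjusted p = 0.9998). The list was higher as a set (camera adjusted p = 0.001497). With an estimated correlation the adjusted p was 0.4409, without tal1 and lmo2 the camera adjusted p was 0.248, and without injected replicate 3 it was 0.1366. Of 13 measured myeloid and leukocyte genes none passed in limma, and the set test gave an adjusted p of 0.2193, or 0.01928 without the filter on dim sequences. With the filter and an estimated correlation the adjusted p was 0.4409. Its member with the smallest p was spi1b, a myeloid ETS factor gene, at 1.03 ± 0.32 (adjusted p = 0.9833). The sequence that stood for spi1b did not pass with the batch block either (adjusted p = 0.05215). Another spi1b sequence, also at 1.03, did not pass without the block (adjusted p = 0.8158), but passed with it (adjusted p = 0.02909). A further spi1b sequence, at 0.92 (adjusted p = 0.6676 without the block), passed in neither fit.

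Presomitic and paraxial mesoderm genes had 36 measured members, of which 0 rose and 0 fell, with 29 lower and 7 higher. The median member difference was -0.22. The growth factor gene fgf17 differed by -0.61 ± 0.20 on the log2 scale and the homeobox gene pax3a by -0.36 ± 0.18, while eve1 differed by 0.63 ± 0.21 and efna1b by 0.38 ± 0.19 (adjusted p = 0.9998 for each). A second fgf17 sequence differed less, by -0.197 ± 0.198. The list was lower as a set (camera adjusted p = 0.0004667). The adjusted p with an estimated correlation was 0.4642, without control replicate 1 the camera adjusted p was 0.05319, and without injected replicate 2 it was 0.09152. In the blocked fit the camera adjusted p was 1.557e-05, or 0.2407 with an estimated correlation, and that of fry was 0.05904. The VEGF and Notch list had the same 3 values in the blocked fit. The median difference between same-numbered samples was -0.28, -0.26 and -0.18 for numbers 1, 2 and 3, which the labels do not tie to shared batches.

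Axial mesoderm, notochord and floor plate genes had 22 measured members, of which none passed and 17 were lower, with a median of -0.21. The BMP antagonist genes nog1 and chrd differed by -0.67 ± 0.27 and -0.38 ± 0.20, and the organiser gene gsc by -0.35 ± 0.21 (log2 ± SE). The set was lower (camera adjusted p = 0.005004). With an estimated correlation the adjusted p was 0.4409, and the camera adjusted p was 0.05319, 0.07845 and 0.1855 without control replicate 1, control replicate 3 and injected replicate 2. In the blocked fit the camera adjusted p was 0.0006718, or 0.2407 with an estimated correlation, and that of fry was 0.05904. Of 46 measured neural plate and brain genes none passed and 33 were lower, with a median of -0.17. Among them gbx2 and ascl1b were higher by 0.88 ± 0.29 and 0.65 ± 0.23, and otx2b differed by -0.40 ± 0.23. This set was lower too (camera adjusted p = 0.01399). The adjusted p with an estimated correlation was 0.5586. The camera adjusted p with the preset correlation was 0.05319 without control replicate 1, 0.06916 without control replicate 3, 0.0608 without injected replicate 1, 0.6195 without injected replicate 2, 0.1901 without both replicate 2 arrays and 0.1397 with median scaling.

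Without the array of injected replicate 2, which had the highest background, the medians of these 3 lists were -0.07, -0.02 and -0.05, and without both replicate 2 arrays they were -0.24, -0.21 and -0.15, in the order presomitic, axial and neural.

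Epidermis and enveloping layer genes had 28 measured members, of which none passed and 18 were higher, with a median of 0.12. Members with the smallest p were bmp7a, higher by 0.79 ± 0.22, the claudin gene cldnb, by 0.56 ± 0.19, and the homeobox gene ved, by 0.68 ± 0.27. The set was higher (camera adjusted p = 0.0004667). With an estimated correlation the adjusted p was 0.2756, and with median scaling the camera adjusted p was 0.1752. Of 23 measured heart, lateral plate and pronephros genes none passed and 14 were higher, with a median of 0.10. The T-box gene tbx2b was higher by 0.98 ± 0.26 (adjusted p = 0.6044), and passed with the batch block (adjusted p = 0.04784), as did a second tbx2b sequence (0.6624 without and 0.04806 with the block). The homeobox gene nkx2.7 was higher by 0.61 ± 0.18 (adjusted p = 0.8299). The set was higher (camera adjusted p = 0.0104). The adjusted p with an estimated correlation was 0.3893. The camera adjusted p was 0.07542 and 0.1366 without injected replicates 1 and 3, 0.8281 without background correction, 0.129 with median scaling, 0.105 with a filter on the mean of all arrays and 0.1336 with the authors' gene table.

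The remaining lists gave no call in the set test, and no member of them passed in limma. Camera adjusted p was 0.05774 for 23 neural crest and placode genes and 0.05234 for 32 cell cycle genes, with medians of 0.08 and 0.11. Both passed with the batch block (adjusted p = 0.04579 and 0.01135), but with an estimated correlation the adjusted p was 0.4409 and 0.7782, or 0.4702 for both in the blocked fit. The cell cycle set turned lower with median scaling. Without injected replicate 2 their adjusted p was 0.0391 and 6.332e-05, and that of the cell cycle set was 0.003266 and 0.004569 without control replicates 1 and 3. The cell cycle set did not pass without injected replicates 1 and 3 (adjusted p = 0.2732 and 0.9407), and it turned lower without control replicate 2 (adjusted p = 0.5886). Adjusted p was 0.2148 for 20 p53 response genes, 0.2765 for 5 interferon response genes and 0.6323 for 11 primordial germ cell genes. Without both replicate 2 arrays, a setting chosen after the data were seen, the p53, interferon, neural crest and cell cycle sets passed as higher (adjusted p = 0.006949, 0.01024, 0.006168 and 0.01024). With the block added, the cell cycle set did not pass (adjusted p = 0.06915), and the other adjusted p were 0.02105, 0.02858 and 0.02105. With all arrays and an estimated correlation, the adjusted p was 0.6539 for the p53 and 0.6341 for the interferon set, or 0.6096 and 0.7611 in the blocked fit. The interferon set also passed with the authors' probe values (adjusted p = 0.02816). The cell cycle and neural crest sets passed without background correction (adjusted p = 0.03177 and 0.02146) and with cyclic loess (adjusted p = 0.02527 and 0.0302). With a filter at the 95th percentile of control probes the cell cycle set passed too (camera adjusted p = 0.04606). Adjusted p was 0.6831 for 23 housekeeping genes, 0.9626 for 30 blastula and early gastrula genes and 0.9783 for 16 endoderm genes. The median was 0.02 in housekeeping and 0.05 in blastula genes while their set tests pointed down, and it was -0.01 in endoderm genes while their set test pointed up.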

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

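All tests of explanations in this part were chosen after the results they bear on had been seen, except the comparison of falls with rises and the draw of matched gene lists.

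The random-sequence control probes, which set each array's background but were not tested themselves, had a median intensity of 865 on the array of injected replicate 2. This was above the highest control array at 370.89. After normalization the background of that array was 7.31 against at most 6.98 in controls, and its mean correlation with the other arrays was 0.931 against 0.953 to 0.971 for the others.

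The limma test called 36 rises and 0 falls. A test that finds falls less readily than rises of the same size is argued against as the whole cause: among sequences with non-overlapping groups and a 2-fold or larger difference, whatever their p, 140 were higher and 5 lower, so that falls came to 3.57% of rises. Simulated data cannot decide this, since their noise was symmetric for rises and falls, without a background floor or a noisier array. In them 0.4% of falls and 0% of rises were recovered at a log2 change of 0.5, and 13.6% and 21.2% at 1. The shares were 70% and 73.6% at 2, and 92% and 88% at 3, with no constant direction. Whether the noise of injected replicate 2 hides falls stays open. With both replicate 2 arrays left out, 94 sequences rose and 0 fell, and with the batch as a block as well, 3 of 232 calls fell, or 1.29%. Array quality weights gave 65 falls among 404 calls, or 16.1%, but only 4 among the 112 calls of 2-fold or more. The weights of injected replicates 1, 2 and 3 were 8.65, 0.18 and 0.498. That fit thus rested mostly on injected replicate 1, and its falls cannot be tied to replicate 2. A mainly activating role of Etsrp in these embryos, a hypothesis, may also account for the pattern and was not tested separately. Since the controls were uninjected, effects of etsrp cannot be told apart from those of the injection itself.

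The presomitic and paraxial mesoderm list was lower in injected embryos with a preset correlation, by a median of -0.22. It was not called with an estimated correlation (camera adjusted p = 0.4642). An intensity-dependent shift left by the normalization is argued against: random lists matched on mean expression had a typical median of -0.013, and 0 of 10000 were as low. Their genes were drawn singly, while this list had an estimated correlation of 0.3, so the draw is no test of the list's change. The cell cycle list, which was not called, lay above 100% of its own matched lists. Injected replicate 2 as the only source is argued against: without both replicate 2 arrays 30 members were lower and 6 higher, with a median of -0.2363 and quartiles of -0.3693 and -0.0642, although without injected replicate 2 alone the median was -0.0667. An earlier stage of the injected embryos stays open: the blastula and early gastrula list had a median of 0.05 and an upper quartile of 0.2135, with members on both sides of 0. A diversion of mesoderm towards vessel precursors is a further hypothesis that may fit, and these arrays of whole embryos hold no test of it.

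The etsrp probe that starts at base 13 read 8.22 (log2) in injected embryos and the other probes 12.42 to 15.93. Whether this is a low reading of first probes in general stays open. A probe's height over background in log2 units was compared with that of its own sequence, which gives no share of signal. By this measure 67 of 997 probes within the first 30 bases of bright sequences (6.72%) stood as low. The median of these 997 probes stood at 71.4% of the sequence's log2 height and the etsrp probe at 13.9%. Probe minus sequence value was -1.72 (log2) in the median and -7.00 for the etsrp probe. A single weak probe, irrespective of position, stays open too, since 162 of 4172 bright sequences (3.88%) had a probe as low. A candidate explanation that stays untested is that the injected RNA lacked this stretch, since its sequence is not given in the sources used here.

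The real grouping of the 6 arrays gave 36 changed sequences, and the highest of the other 9 groupings into 3 and 3 gave 0, for 2-fold changes as well. Only 1 of the 10 groupings, the real one, gave as many, and 10 groupings are too few for a share below 0.05. Of the 4 groupings that part all 3 same-numbered pairs, the real one had 593 sequences at an unadjusted p below 0.05, and the others 137, 21 and 431. The 4 groupings with both replicate 2 arrays on the same side gave 1266 to 3755, and the other 2, which part only these arrays, gave 379 and 339, so the largest counts go with the replicate 2 arrays. Without both replicate 2 arrays the block moved the adjusted calls from 94 to 232. The counts at an unadjusted p below 0.05 moved less, from 580 higher and 117 lower to 601 and 152. With so few arrays the blocked fit has little noise of its own to estimate, so whether structure by batch remains cannot be told.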

How the results depend on the processing

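Array weights, the authors' normalized probe values, fits without both replicate 2 arrays, the block with offset 0 and lists with members removed were chosen after seeing the data; the others were planned. In all fits the etsrp rise passed, between 6.02 without background correction and 7.43 with the authors' gene table, and none of the single genes rerun in each fit (the largest rises and the members named from called lists) reversed. Fold changes of dim genes are limited by signal over background: 22 of the 36 changed sequences were dim in all controls.

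The 36 changed sequences, all 2-fold as fitted, became 9 without background correction, 8 with median scaling, 94 without both replicate 2 arrays and 142 with the block and offset 0, the same for 2-fold changes. Array quality weights, whose fit did not fully converge and rested mostly on injected replicate 1, gave 404 (339 up and 65 down, with 112 of the 404 being 2-fold). Leaving out 1 array, which also leaves fewer samples, gave 5 to 59. The cause of these and the other shifts was not tested. An unadjusted limma p up to 0.05 gave 593 and a two-sample test without pooled variance 705, or 4 after adjustment. Both unadjusted counts are below the share of 0.05 expected with no change. With the replicate block, the count was 126, of which 118 were 2-fold, and 232, of which 136 were 2-fold, without both replicate 2 arrays; the pairing rests on the check of shared deviations. Set beside the main fit, the block changed no other call of a named gene or of a list with the preset correlation than those given above; with offset 0 it moved the interferon list from 0.06286 to 0.04815. Slide or scan as a block could not be run, since each array was its own slide.

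Of the 18 lists, 9 were called, 3 with an estimated correlation and 3 by fry; leaving out 1 array gave 7 to 9.

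Lists without a call changed direction in places, the cause untested. The endoderm list turned lower (adjusted p) with offset 0 (0.8319), no background correction (0.7225), median scaling (0.5721), cyclic loess (0.9275), probe means (0.7648), no filter (0.3852), the 95th percentile filter (0.9196), the authors' gene table (0.9812), the block (0.9637), the authors' probe values (0.934), both replicate 2 arrays left out (0.5612, blocked 0.5619), the block with offset 0 (0.789), fry (0.9885) and means over sequences (0.791), and spanned 0.1242 to 0.999 with 1 array left out. The germ cell list reversed without background correction (0.8479), the cell cycle list with median scaling (0.7708), and the blastula list with means over sequences (0.8981). The housekeeping list reversed with cyclic loess (0.9275) and without both replicate 2 arrays (0.7751, blocked 0.9762). With 1 array left out, some directions of these and the p53 list turned, and adjusted p spanned 0.05319 to 0.999 for germ cell, 6.332e-05 to 0.9407 for cell cycle, 0.3151 to 0.8459 for blastula, 0.1506 to 0.8998 for housekeeping and 0.05683 to 0.8402 for p53 genes.

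For single genes, 742 other values kept direction and side of the threshold, 28 newly passed and 55 no longer passed; for single lists these counts were 369, 22 and 34.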

Other observations

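Besides agtr2 and fli1rs, 5 genes that rose were in no list and outside the naming rule, and are named after their values were seen. The zinc finger cofactor gene zfpm2b rose by 2.04 ± 0.22 on the log2 scale (limma adjusted p = 0.01758), mcamb, which encodes a cell adhesion molecule, by 2.13 ± 0.26 (adjusted p = 0.02712) and nrgnb at least 3.76-fold (adjusted p = 0.01922). The keratin gene krt18b rose at least 2.53-fold (adjusted p = 0.03986) on 1 sequence, and its other sequence did not pass (adjusted p = 0.5748). The gene cd74b, which encodes an MHC class II associated chain, had 5 sequences on the array. One rose, at least 2.42-fold (adjusted p = 0.03491), and the other 4 were higher and did not pass, with adjusted p from 0.05135 to 0.1455, and passed with the batch block (adjusted p from 0.007087 to 0.03074).

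The fit with the batch number as a block called 58 gene symbols, of which 33 were in no list. They include genes known from different tissues, and no theme among them was tested. Of those that passed only with the block, the smallest blocked adjusted p belonged to clic2 (0.00113), svila (0.006219) and myh11a (0.006854), named after their values were seen. Without the block their adjusted p was 0.0619, 0.1066 and 0.1256. The svila level was higher by 1.63 ± 0.20 on the log2 scale (SE of the blocked fit), and clic2 and myh11a were dim in all controls.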
